A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

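RNA of 15 samples was measured on Affymetrix Yeast Genome 2.0 arrays, which carry probe sets for S. cerevisiae and for S. pombe. Per the labels' protocols, BY4741 cells and a derivative without mitochondrial DNA were grown with shaking at 30 °C for 3 days in YPD with 2% glucose and separated by density on Percoll. RNA was taken with TRIzol, treated with DNase and cleaned on columns, and 100 ng of total RNA was labelled with biotin, per the labels' protocols. The deposited values are log2 signals that the authors made by RMA in Affymetrix Expression Console, per the labels, which give no version of either. RMA sets all arrays to the same distribution of probe signals and then summarizes these per probe set, so that values measure a transcript relative to the others on the array. The distributions of the summarized values were not identical. Their medians averaged 2.784 in WT high density, 2.714 in WT low density and 2.676 in Rho0 low density.

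The table held 10928 probe sets for 15 arrays with values from 1.28 to 14.6, and 0 columns were not used. The given annotation named 1 gene for 7244 probe sets, several genes for 1 and none for 3683, of which 166 were control probe sets. Of the probe sets with 1 named gene, 5498 named a gene of the S. cerevisiae reference table. The remaining 1746 were taken as S. pombe. A gene with several probe sets (47 genes) was represented by that with the highest mean, which left 5449 genes, 4950 with a standard name. Probe sets that may bind related genes represented 98 (s_at) and 17 (x_at) genes. The calls of probe sets for the same gene were opposite in 2, 1 and 2 of the 47 genes in the 3 comparisons. The background level, the 95th percentile of the S. pombe probe set means, was 2.56 log2. Controls were 36 poly-A spike-in and 27 hybridization probe sets. Of the 8 genes on mitochondrial DNA chosen for a check of the Rho0 label none was named in the annotation, so that they were not analysed here. The labels name no genome build, so no coordinates are given. A reference table of strain S288C served only for names, for the order of genes and to tell S. cerevisiae from S. pombe probe sets.

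The 3 comparisons were WT low density against WT high density, Rho0 low density against WT low density and Rho0 low density against WT high density, each with 5 arrays per group. Group means were fitted to all 15 arrays in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, without a trend, with 12 residual degrees of freedom, and p was adjusted by Benjamini and Hochberg over 5449 genes. A gene was called at an adjusted p under 0.05. The median SE of a difference was 0.152 log2. Gene lists (28 tested) were tested with camera at its preset correlation of 0.01, two-sided, adjusted over 84 list tests, and beside it with an estimated correlation and with fry. Exact two-sided permutation tests compared measures per array, adjusted over 39 tests, with 0.00794 as the smallest possible p. S. pombe probe sets were tested in limma on their own. The groups, the comparisons, the tests, the lists, the rule for named genes and most alternatives were chosen before the data were examined.

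Genes named are the 10 largest positive and the 10 largest negative log2 fold changes in the first and second comparisons and the 5 largest each way in the third, among genes with an adjusted p under 0.05, no overlap between the values of the groups, a mean above the background level in the higher group and a standard name. For each list the 2 called members with the largest change either way are named too. The result of 1 of the 28 lists and the genes named with it are not reported here, although the counts of lists and of genes called include them. The list names KRE11 and LAP4 were read as TRS65 and APE1. ACO1, PDR10 and AGA2 in the first comparison, the strain markers and the genes under other observations were chosen after their values were seen. Where the mean of the lower group was not above the background level the fold change is given as at least the ratio to that level.

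The scripts were tested on simulated data with 5449 genes. Of genes changed by 0.5 log2, 24%, 38% and 50% were recovered in the 3 comparisons, of those changed by 1 log2 94%, 88% and 92%, and of those changed by 2 or 3 log2 100%. False calls made up 5.98%, 4.89% and 5.05% of the calls, and a shifted list was recovered with 0 of 27 other lists called. The simulated noise was independent between genes, so this does not show how the list test behaves where genes vary together.

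Alternatives were a fit of only the 10 arrays compared, the replicate number as a block, eBayes with a trend and robust, genes above background only, quantile normalization of the S. cerevisiae genes alone, arrays shifted to the same S. pombe median or the same S. cerevisiae median, the mean of the probe sets of a gene, array weights, treat against a 1.5-fold change, and each array left out in turn. Added after the data were seen were arrays scaled (shifted) to the same mean of the poly-A spike-in controls, probe sets that may bind related genes left out, and the arrays numbered 1 left out. The closing section gives their effect.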

Results

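The transcriptomes of 3 kinds of cells of the budding yeast Saccharomyces cerevisiae were measured on Affymetrix Yeast Genome 2.0 arrays, with 5 biological replicates per group and 15 arrays in all. BY4741 is a haploid laboratory strain of mating type a. Its cells were taken after 3 days in rich medium (YPD) that held 2% glucose at the start. Percoll centrifugation, which sorts cells by buoyant density, gave a WT high density and a WT low density fraction. The group named Rho0 low density is the low density fraction of a derivative without mitochondrial DNA, which cannot respire. The dense fraction of such cultures is known from other work to be rich in quiescent cells, and the light fraction in cells that are not quiescent. Values are log2 signals after RMA, so every change below is relative to the other transcripts on the array, and the number of arrays limits the precision. Of 5449 S. cerevisiae genes, 5113 ± 33.7 (mean ± SD, n = 5) were above the background level of 2.56 in WT high density, 4860 ± 25 in WT low density and 5032 ± 27.2 in Rho0 low density. Of the 4 genes known to be deleted in BY4741, URA3 (means from 2.14 to 2.26) and MET17 (2.27 to 2.42) stayed under that level, LEU2 (2.67 to 2.90) lay just above it and HIS3 (5.87 to 6.09) well above it. The HIS3 allele of this strain is known to lack only a part of the gene.

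The first principal component held 60.8% of the variance between arrays and the second 27.3%, and the 5 arrays of each group lay together. WT high density arrays had first-component scores between 43.2 and 48.8. The WT low density arrays lay within 4 of 0 and Rho0 low density arrays between -56.6 and -46.1. Rho0 low density replicate 1 held the lowest of these scores, and the next lowest was -49.1. The farthest pair of arrays within a group differed by 0.58 log2 (root mean square over genes) in WT high density, 0.48 in WT low density and 0.40 in Rho0 low density.

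**Figure D1:**
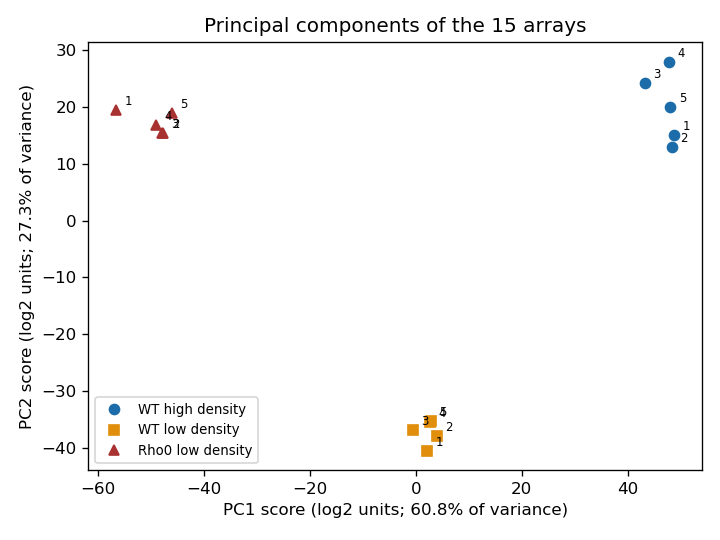
Scores of the 15 arrays on the first (x axis, 60.8% of variance) and second (y axis, 27.3%) principal components of the log2 signals of S. cerevisiae genes, in log2 units. Each point is an array and the digit beside it its replicate number; the arrays of each group lie together, and Rho0 low density replicate 1 lies farthest to the left at -56.6.

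Several control probe sets differed between groups. The probe set for the 5′ part of 25S ribosomal RNA read 7.87 ± 0.13 in WT high density, 11.36 ± 0.45 in WT low density and 7.75 ± 0.27 in Rho0 low density (mean ± SD, n = 5). The WT low density arrays were higher than the WT high density arrays with an exact two-sided permutation p = 0.00794, the smallest that 5 against 5 arrays allow, and an adjusted p = 0.0119 over 39 such tests. The middle of the same RNA read 10.99 ± 0.32, 14.17 ± 0.04 and 13.28 ± 0.15, and its 3′ part 13.94 ± 0.15, 14.16 ± 0.02 and 14.24 ± 0.02, in the same order of groups. The poly-A spike-in RNAs, bacterial transcripts added to the samples before labelling, averaged 10.12 ± 0.21, 10.34 ± 0.24 and 9.66 ± 0.24. Rho0 low density was lower than WT low density in them by an exact permutation p = 0.00794. Hybridization controls averaged 11.51 ± 0.31, 11.67 ± 0.24 and 11.29 ± 0.30, and the last group differed from WT low density by an exact p = 0.0635.

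**Figure D2:**
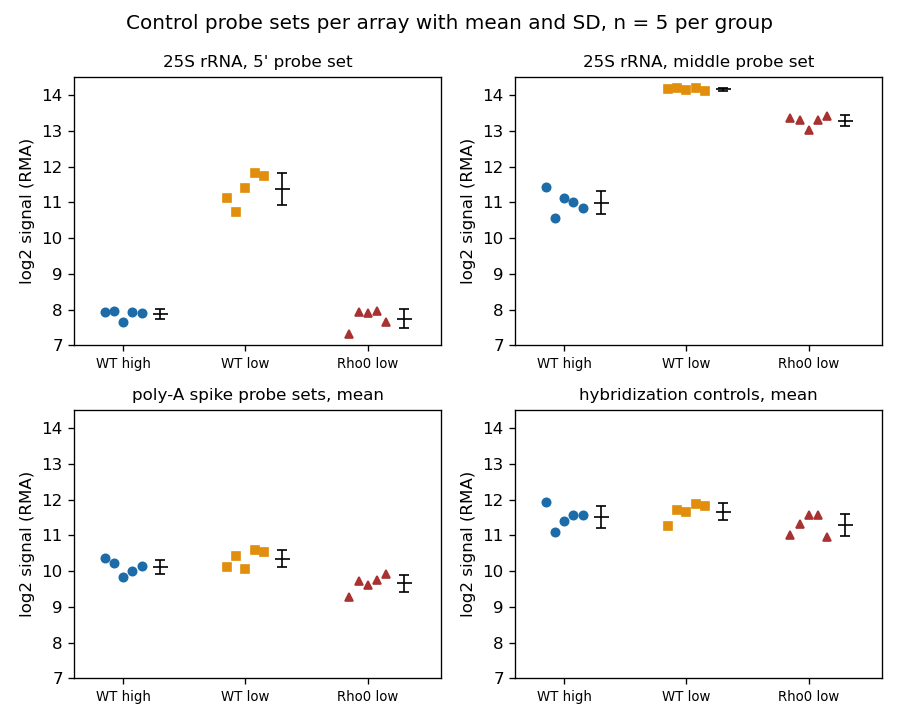
Signal of 4 kinds of control probe sets (y axes, log2) per array in the 3 groups (x axes), with bars for mean and SD of 5 arrays. The 25S ribosomal RNA 5′ probe set reads 11.36 on average in WT low density against 7.87 and 7.75 in the other groups, and the poly-A spike-in probe sets are lowest in Rho0 low density at 9.66.

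The first comparison asked how the light and the dense cells of wild-type cultures differ. WT low density cells had more mRNA of respiratory chain, chaperone and pleiotropic drug resistance genes than WT high density cells. Less mRNA was found for ribosome assembly, cell cycle and sporulation genes. Of these groups pleiotropic drug resistance alone kept its call with an estimated correlation (adjusted p = 0.0226, against 0.173 to 0.329 for the others). The cell cycle group also lost its call after quantile normalization of the S. cerevisiae genes alone (0.0923). PRM8 (YGL053W), a pheromone-regulated membrane protein, rose most of the genes named by the fixed rule, 19.7-fold from 3.12 ± 0.36 to 7.42 ± 0.20 (log2 signal, mean ± SD, n = 5). MPC2 (YHR162W), a subunit of the mitochondrial pyruvate carrier, rose 14.7-fold from 7.87 ± 0.20 to 11.74 ± 0.13, and CYC1 (YJR048W), the main cytochrome c, rose 10.5-fold from 5.72 ± 0.58 to 9.11 ± 0.62. NCA3 (YJL116C), a cell wall protein of the SUN family, fell from 14.09 ± 0.09 to 10.19 ± 0.11, or 14.9-fold. The meiotic inducer gene IME1 (YJR094C) fell 7.53-fold, and the cyclin gene CLN3 (YAL040C) fell as well.

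The 10 largest rises also held MSF1, for the mitochondrial phenylalanyl-tRNA synthetase, at 3.94 ± 0.16 log2 (difference ± SE), EHT1, for an ethyl ester synthase, at 3.82 ± 0.21, and AIM17 at 3.61 ± 0.11. They were completed by YGP1, for a secreted glycoprotein of starved cells (3.53 ± 0.19), CAX4, for a dolichyl pyrophosphate phosphatase (3.51 ± 0.15), COX19, for a cytochrome c oxidase assembly factor (3.51 ± 0.24), and ZNF1, for a regulator of respiratory growth (3.33 ± 0.10). The largest falls were those of SRL4 (-4.13 ± 0.27) and MCH2, for a relative of monocarboxylate permeases (-4.02 ± 0.22). ERR3, an enolase-related gene read by a probe set that may bind related genes, stood at -3.80 ± 0.18 after NCA3, and the hexose transporter gene HXT14 at -3.48 ± 0.26. SPO19, a gene of sporulating cells, was at least 10.4-fold lower, since its WT low density mean was under the background level. CRF1, FIG1, SEO1 and SHH3 lay between -3.21 and -3.18. For all 20 genes the 5 values of each group did not overlap and the limma adjusted p was at most 2.78e-09.

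Of the 40 nuclear genes for the respiratory chain and ATP synthase, 28 rose and 2 fell (28 and 3 adjusted over the list alone), led by CYC1 and the ATP synthase gene ATP2 (2.62 ± 0.28). The list averaged 1.05 log2 above the other genes (camera adjusted p = 2.23e-07; adjusted p = 0.329 with an estimated correlation). In the TCA cycle list 10 of 16 genes rose and 2 fell, with the citrate synthase gene CIT1 at 1.77 ± 0.17 and the fumarase gene FUM1 at 1.51 ± 0.27 (adjusted p = 0.00343, and adjusted p = 0.374 with an estimated correlation). Among 7 targets of the retrograde pathway, which adjusts nuclear genes to the state of mitochondria, 6 rose, among them DLD3 (1.61 ± 0.17), and ACO1 fell. That list had an adjusted p = 0.00597 (adjusted p = 0.391 with an estimated correlation). It shared CIT1, ACO1, IDH1 and IDH2 with the TCA cycle list. The TCA cycle list shared SDH1, SDH2, SDH3 and SDH4 with the respiratory chain list, so that these results are not independent.

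Trehalose and glycogen metabolism had 14 of 18 genes up and 2 down, with the glycogen synthase gene GSY2 at 2.73 ± 0.14 and the trehalose synthase subunit gene TSL1 at 2.11 ± 0.12 (adjusted p = 4.98e-05; adjusted p = 0.327 with an estimated correlation). Heat shock proteins and chaperones had 17 of 23 genes up and 2 down, with the Hsp70 genes SSA4 (3.14 ± 0.14) and SSA2 (2.94 ± 0.13) in front (adjusted p = 4.6e-06; adjusted p = 0.327 with an estimated correlation). Proteasome genes rose in 16 and fell in 3 of 33 cases (16 and 2 adjusted over the list alone), with PRE5 at 1.92 ± 0.18 and RPT6 at 1.25 ± 0.19 (adjusted p = 0.00282; adjusted p = 0.44 with an estimated correlation). All of these lists moved while the 25S 5′ signal was 3.49 log2 higher in WT low density.

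Pleiotropic drug resistance genes rose in 12 of 13 cases, with the efflux pump gene PDR5 at 2.64 ± 0.10 and the polyamine exporter gene TPO1 at 2.43 ± 0.13, while PDR10 fell. This call held with an estimated correlation (adjusted p = 7.62e-07 and 0.0226). Iron regulon genes rose in 11 and fell in 5 of 23 cases, led by the siderophore transporter gene SIT1 (2.49 ± 0.14) and the mitochondrial iron carrier gene MRS4 (1.86 ± 0.18). Their adjusted p = 0.0161 became an adjusted p = 0.379 with an estimated correlation, and 0.0625 after quantile normalization of the S. cerevisiae genes alone. Histone genes rose in 7 of 9 cases, with HTZ1 at 1.39 ± 0.11 and HHT2 at 1.24 ± 0.10 (adjusted p = 0.00206; adjusted p = 0.302 with an estimated correlation).

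Genes specific to the a mating type rose in 5 of 6 cases, with the pheromone gene MFA2 at 1.98 ± 0.11 and the receptor gene STE2 at 1.63 ± 0.14, and AGA2 fell (adjusted p = 0.0133; adjusted p = 0.327 with an estimated correlation). All 4 genes specific to the other mating type fell, by 2.29 ± 0.20 for MF(ALPHA)2 and by 1.30 ± 0.17 for the agglutinin gene SAG1, although the list did not pass (adjusted p = 0.117). Sporulation and meiosis genes, markers of another cell type, fell in 13 of 17 cases and rose in 0, with IME1 at -2.91 ± 0.23 and the recombinase gene DMC1 at -1.76 ± 0.12 (adjusted p = 0.00916; adjusted p = 0.173 with an estimated correlation).

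Ribosome biogenesis genes fell in 25 of 34 cases and rose in 1. NOP4, for a nucleolar protein, stood at -2.73 ± 0.13, and SSF1, for another assembly factor, was at least 5.29-fold lower (adjusted p = 0.000305; adjusted p = 0.327 with an estimated correlation). Cytosolic ribosomal protein genes fell in 67 of 127 cases and rose in 16, with RPS11A at -2.47 ± 0.15 and RPL38 at -2.40 ± 0.19. Their adjusted p = 0.013 became an adjusted p = 0.656 with an estimated correlation, and 0.0614 without WT high density replicate 3. Fatty acid oxidation and peroxisome genes fell in 16 of 23 cases and rose in 2 (17 and 2 adjusted over the list alone), with the acyl-CoA oxidase gene POX1 at -2.02 ± 0.12 and PEX11 at -1.97 ± 0.12 (adjusted p = 0.00811; adjusted p = 0.417 with an estimated correlation). Cell cycle and DNA replication genes fell in 21 of 33 cases and rose in 2, with CLN3 at -2.59 ± 0.21 and the helicase subunit gene MCM2 at -1.94 ± 0.18. Their adjusted p = 0.0149 became an adjusted p = 0.217 with an estimated correlation, and 0.0923 after quantile normalization of the S. cerevisiae genes alone.

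Members of other lists moved both ways. Mitochondrial ribosome genes rose in 20 and fell in 16 of 65 cases (19 and 16 adjusted over the list alone), with MRPS35 at 2.38 ± 0.13 and MRPS16 at -1.74 ± 0.13. Glyoxylate cycle and gluconeogenesis genes rose in 2 and fell in 7 of 14 cases, with PCK1, for the key gluconeogenic enzyme, at 2.28 ± 0.20 and its regulator gene SIP4 at -1.69 ± 0.15. Glycolysis and fermentation genes rose in 5 and fell in 10 of 21 cases, with HXK1 at 3.11 ± 0.20 and PDC6 at -2.30 ± 0.18. The WT low density mean of PDC6 (2.57) lay at the background level. Hexose transporter genes rose in 3 and fell in 9 of 14 (4 and 9 adjusted over the list alone), with HXT10 at -2.75 ± 0.18. Antioxidant genes rose in 11 and fell in 11 of 26 cases, with the peroxiredoxin gene TSA2 at 2.80 ± 0.23 and the glutathione reductase gene GLR1 at 2.58 ± 0.11. Stationary phase genes rose in 2 and fell in 8 of 13 cases (2 and 9 adjusted over the list alone), with YGP1 up and SNO1 at -2.40 ± 0.15. Autophagy and vacuolar protease genes rose in 7 and fell in 14 of 27 cases (7 and 15 adjusted over the list alone), although the largest changes were rises of APE1 (2.08 ± 0.18) and ATG15 (2.05 ± 0.18). Amino acid biosynthesis genes rose in 13 and fell in 11 of 45 cases (12 and 11 adjusted over the list alone), with ILV5 at -2.01 ± 0.31 and HIS1 at 1.44 ± 0.12. Ergosterol genes rose in 8 and fell in 9 of 24 cases, with MVD1 at 1.36 ± 0.13 and ERG5 at -1.33 ± 0.18, and hypoxic genes rose in 8 and fell in 6 of 16, with HEM13 at 2.20 ± 0.17 and TIR2 at -2.03 ± 0.21. Reference transcripts used in quantitative PCR rose in 3 and fell in 3 of 9 cases (3 and 4 adjusted over the list alone), with TUB2 at 1.25 ± 0.16 and TRS65 at -1.19 ± 0.15. None of these lists passed the camera test, their adjusted p running from 0.118 to 0.991. The larger side of the counts turned or evened out with at least 1 other scaling of the arrays for the mitochondrial ribosome, amino acid, ergosterol and hypoxic lists. The antioxidant (11 and 11) and reference lists (3 and 3) had even counts and so no larger side. The median and the mean differed in sign for amino acid genes (-0.08 and 0.06) and ergosterol genes (-0.14 and 0.04), and the test pointed up for glycolysis at a mean of -0.12. For autophagy it pointed down although the list mean lay within 0.01 log2 of the other genes.

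In this comparison 3663 of 5449 genes (67.2%) passed an adjusted p of 0.05 in limma, 1425 higher and 2238 lower in WT low density, with a median size of 0.88 log2 among them. At least 2-fold changes numbered 638 up and 887 down, and 16 of the 28 lists were called, 11 up and 5 down. The median change of all genes was -0.17 log2, and the split of called genes moved to 1774 higher and 1792 lower after quantile normalization of the S. cerevisiae genes alone, and to 880 higher and 2462 lower with arrays scaled to the poly-A spike-in controls. Except where given, the list counts were the same adjusted over the list alone.

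**Figure D3:**
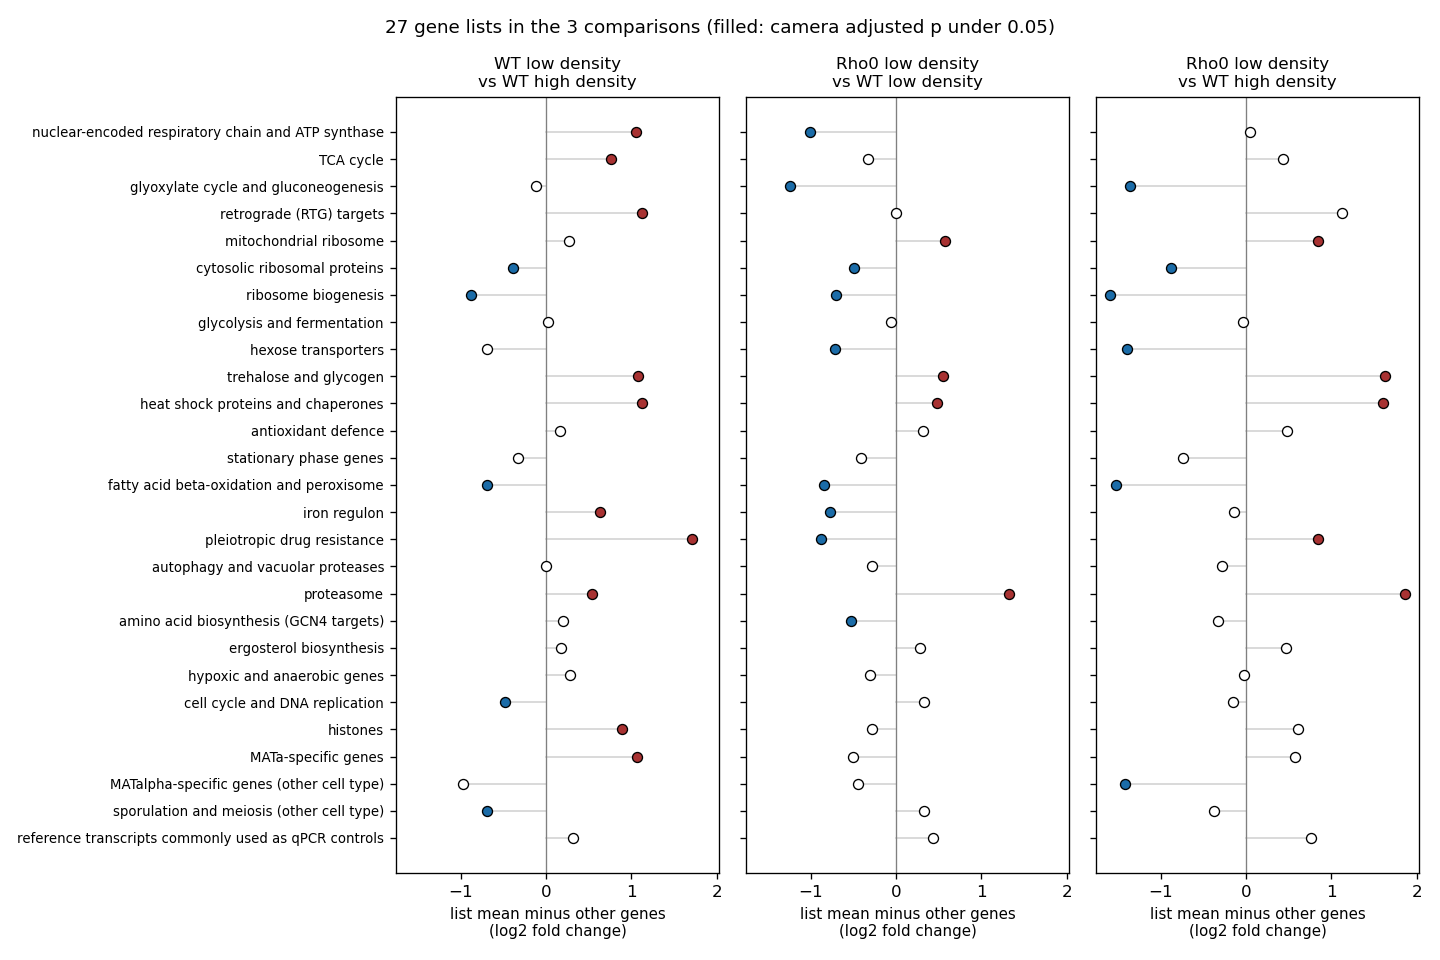
Mean log2 fold change of each of 27 gene lists minus that of all other genes (x axis, log2) in the 3 comparisons (panels), filled where the camera adjusted p was under 0.05 (red up, blue down). Pleiotropic drug resistance genes stand highest of these lists in the first panel at 1.71 and proteasome genes in the others at 1.32 and 1.86, and the respiratory chain list lies at 1.05 in the first and -1.01 in the second panel; in the second panel the rose and fell counts of 8 lists called down turned with arrays scaled to the poly-A spike-in controls.

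The second comparison set Rho0 low density against WT low density, cells of like density with and without mitochondrial DNA. ADH2 (YMR303C), the alcohol dehydrogenase that oxidizes ethanol, fell 118.5-fold in Rho0, from 12.46 ± 0.16 to 5.57 ± 0.27 (log2 signal, mean ± SD, n = 5). Genes for 3 transporters followed: PTR2 (YKR093W), for peptides, fell 69.2-fold from 10.52 ± 0.17 to 4.40 ± 0.27, MEP2 (YNL142W), for ammonium, 58.2-fold from 12.75 ± 0.21 to 6.89 ± 0.32, and OPT2 (YPR194C), for oligopeptides, 42.9-fold. Proteasome genes rose in 31 of 33 cases, and nuclear genes of the respiratory chain fell in 26 and rose in 4 of 40 (13 and 9 with arrays scaled to the poly-A spike-in controls), with COX6 (YHR051W) down 6.16-fold. Both lists had an adjusted p = 0.327 with an estimated correlation. ECM29 (YHL030W), for a scaffold that binds the proteasome and is not on that list, rose 13.8-fold from 4.66 ± 0.07 to 8.45 ± 0.06. The actin gene ACT1 (YFL039C), often used as a reference, rose 4.60-fold.

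Further large falls were those of the proline permease gene PUT4 (-5.28 ± 0.13 log2, difference ± SE), the methionine permease gene MUP3 (-5.19 ± 0.16), the formate dehydrogenase gene FDH1 (-5.13 ± 0.13) and the acetate transporter gene ADY2 (-4.85 ± 0.14). The weak acid pump gene PDR12 stood at -4.72 ± 0.16 and EFM4, for a protein methyltransferase, at -4.25 ± 0.13. COS12 was at least 9.12-fold higher, its WT low density mean being under the background level. BUL1, for a ubiquitin ligase adaptor, rose by 3.25 ± 0.16, SRB7, for a Mediator subunit, by 3.24 ± 0.30, and the wall protein gene PIR1 by 3.06 ± 0.10. SOR2, a sorbitol dehydrogenase gene read by a probe set that may bind related genes, was at 3.12 ± 0.18. The remaining rises among the 10 largest were those of HXT13, for a polyol and hexose transporter (2.95 ± 0.18), the invertase gene SUC2 (2.91 ± 0.16), the polyamine acetyltransferase gene PAA1 (2.82 ± 0.18) and EMP46, for a cargo receptor of the secretory pathway (2.79 ± 0.11). None of these 20 genes had overlapping groups, and their limma adjusted p was at most 1.97e-08.

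**Figure D4:**
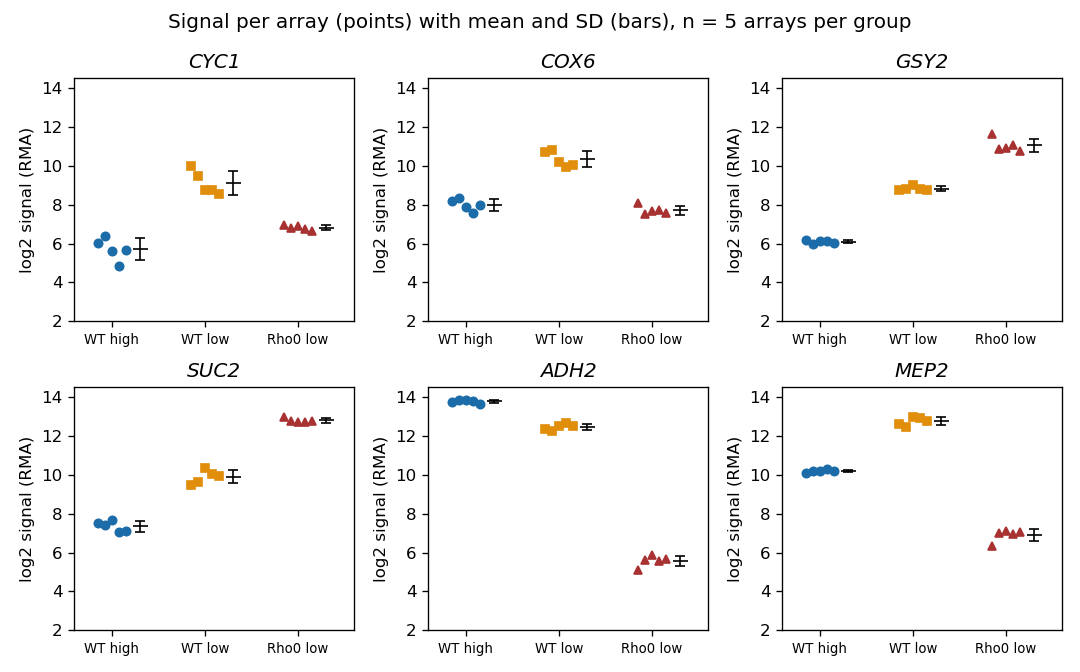
Signal (y axes, log2) of CYC1, COX6, GSY2, SUC2, ADH2 and MEP2 on each array of the 3 groups (x axes), with bars for mean and SD of 5 arrays. CYC1 is highest in WT low density at 9.11, GSY2 and SUC2 rise from WT high density over WT low density to Rho0 low density, and ADH2 stands at 5.57 in Rho0 low density against 12.46 in WT low density.

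Proteasome genes rose in 31 of 33 cases and fell in 1, and the list lay 1.32 log2 above the other genes, with RPN2 at 2.62 ± 0.17 and PRE9 at 2.54 ± 0.15 (adjusted p = 1.66e-07; adjusted p = 0.327 with an estimated correlation). These rises went with a 25S 5′ signal lower in Rho0 (a difference of -3.61, exact p = 0.00794) and a mean 3′ minus 5′ difference of 7 control messenger RNAs greater by 0.263 (exact p = 0.0238). The latter came mostly from SRB4 (2.89 in WT low density and 4.96 in Rho0). The difference rose less for EAF5, RIP1 and WBP1 and fell for ACT1, SPT15 and TDH1. The mean of the 7 was chosen after the data were seen, and its p was not adjusted. Rho0 low density replicate 1 stood apart in the proteasome list, at a mean of 9.206 against 8.614 to 8.725 in the other 4 arrays. It did so too in the mitochondrial ribosome (7.035 against 6.645 to 6.712), heat shock (11.02 against 10.68 to 10.76) and trehalose and glycogen lists (9.954 against 9.61 to 9.708). Mitochondrial ribosome genes rose in 44 and fell in 7 of 65 cases (45 and 7 adjusted over the list alone), with MRPL32 at 2.76 ± 0.21 and MRPL4 at 2.45 ± 0.26 (adjusted p = 0.00103; adjusted p = 0.417 with an estimated correlation). Heat shock proteins and chaperones rose in 19 and fell in 1 of 23 cases, with SSE2 at 1.47 ± 0.17 and HSP82 at 1.34 ± 0.16. Their adjusted p = 0.0141 became an adjusted p = 0.44 with an estimated correlation, and 0.0504 with arrays scaled to the poly-A spike-in controls. Trehalose and glycogen genes rose in 15 and fell in 3 of 18 cases, with GSY2 at 2.22 ± 0.14 and the phosphoglucomutase gene PGM2 at 1.63 ± 0.11. Their adjusted p = 0.0348 became an adjusted p = 0.457 with an estimated correlation, and 0.0919 with arrays scaled to the poly-A spike-in controls.

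Respiratory chain and ATP synthase genes fell in 26 of 40 cases and rose in 4, against 13 and 9 and a list mean of -0.13 in place of -0.81 with arrays scaled to the poly-A spike-in controls, with COX6 at -2.62 ± 0.18 and CYC1 at -2.29 ± 0.27. The list lay 1.01 log2 under the other genes (a difference of -1.01, adjusted p = 1.6e-07; adjusted p = 0.327 with an estimated correlation). Rho0 low density replicate 1 stood apart in this list (9.797 against 9.458 to 9.548 in the other 4 arrays), in cytosolic ribosomal proteins (8.145 against 7.908 to 7.94) and in fatty acid oxidation (7.098 against 6.928 to 6.969). The remaining falls are given with the counts found when arrays were scaled to the poly-A spike-in controls, which were 0.68 log2 lower in Rho0 (a difference of -0.68). Glyoxylate cycle and gluconeogenesis genes fell in 6 and rose in 2 of 14 cases (4 and 7 so scaled), with ADY2 at -4.85 ± 0.14 and the fructose bisphosphatase gene FBP1 at -3.88 ± 0.17 (adjusted p = 0.00543; adjusted p = 0.379 with an estimated correlation). Fatty acid oxidation and peroxisome genes fell in 11 and rose in 4 of 23 cases (7 and 10 so scaled), with POX1 at -3.73 ± 0.12 and the peroxisomal catalase gene CTA1 at -3.62 ± 0.19 (adjusted p = 0.00514; adjusted p = 0.4 with an estimated correlation). Hexose transporter genes fell in 8 and rose in 1 of 14 cases (4 and 5 so scaled). HXT1 stood at -2.00 ± 0.15 and, upward, HXT14 at 2.02 ± 0.26 (adjusted p = 0.0073; adjusted p = 0.345 with an estimated correlation).

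Cytosolic ribosomal protein genes fell in 57 and rose in 9 of 127 cases (56 and 9 adjusted over the list alone), against 7 and 52 with arrays scaled to the poly-A spike-in controls. RPS27A stood at -2.85 ± 0.13 and RPL23A at -1.97 ± 0.11 (adjusted p = 4.31e-06; adjusted p = 0.463 with an estimated correlation). Ribosome biogenesis genes fell in 13 and rose in 2 of 34 cases (6 and 13 so scaled), with IMP4 at -2.99 ± 0.16 and RLP7 at -2.75 ± 0.16 (adjusted p = 0.000586; adjusted p = 0.327 with an estimated correlation). Iron regulon genes fell in 13 and rose in 4 of 23 cases (6 and 10 so scaled), with SIT1 at -2.87 ± 0.14 and the iron permease gene FTR1 at -2.19 ± 0.15 (adjusted p = 0.00222; adjusted p = 0.327 with an estimated correlation). Pleiotropic drug resistance genes fell in 7 and rose in 2 of 13 cases (5 and 6 so scaled), with RSB1 at -2.71 ± 0.13 and PDR16 at -2.05 ± 0.13 (adjusted p = 0.00393; adjusted p = 0.234 with an estimated correlation). Amino acid biosynthesis genes fell in 17 and rose in 13 of 45 cases (8 and 23 so scaled, and 14 and 15 with arrays shifted to the same S. pombe median), with CPA1 at -3.11 ± 0.29 and ILV3 at -2.81 ± 0.12 (adjusted p = 0.0251; adjusted p = 0.44 with an estimated correlation).

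Cell cycle genes rose in 18 and fell in 1 of 33 cases (8 and 5 after quantile normalization of the S. cerevisiae genes alone), with CLB5 at 2.03 ± 0.17 and RFA1 at 1.70 ± 0.20 (adjusted p = 0.181). Sporulation genes rose in 8 and fell in 0 of 17 (6 and 3 with arrays shifted to the same S. cerevisiae median), with IME2 at 1.65 ± 0.15 and DIT1 at 1.56 ± 0.13 (adjusted p = 0.262). Reference transcripts rose in 6 and fell in 2 of 9 cases, with ACT1 at 2.20 ± 0.19 and TUB2 at 1.46 ± 0.16 (adjusted p = 0.38). Glycolysis and fermentation genes rose in 15 and fell in 1 of 21, against 8 and 5 and a mean turned from 0.13 to -0.13 with arrays shifted to the same S. cerevisiae median. The hexokinase gene HXK1 at 1.74 ± 0.20 and ADH2 were the extremes, and the test pointed up although the list mean lay 0.05 log2 under the other genes (a difference of -0.05, adjusted p = 0.302). Antioxidant genes rose in 16 and fell in 4 of 26 cases, with AHP1 at 2.09 ± 0.13 (adjusted p = 0.173, and 0.0382 after quantile normalization of the S. cerevisiae genes alone). Ergosterol genes rose in 15 and fell in 4 of 24, with ERG11 at 1.43 ± 0.19 and ERG12 at 1.32 ± 0.24. Retrograde targets rose in 5 and fell in 2 of 7 cases (3 and 2 with arrays shifted to the same S. cerevisiae median), with IDH2 at 0.89 ± 0.25, whose groups overlapped, and DLD3 at -1.25 ± 0.17. Mixed counts were found for the TCA cycle (5 rose and 6 fell of 16, or 6 and 6 adjusted over the list alone, SDH2 at -1.71 ± 0.29 and KGD2 at -1.26 ± 0.14) and for autophagy (7 and 8 of 27, ATG15 at -1.72 ± 0.18 and PRB1 at -1.66 ± 0.12). Hypoxic genes rose in 6 and fell in 4 of 16 cases, with the desaturase gene OLE1 at -2.91 ± 0.12 and ROX1 at -2.65 ± 0.26. Stationary phase genes rose in 3 and fell in 6 of 13, with SNZ1 at -1.67 ± 0.14 and SNO1 at -1.55 ± 0.15. Histone genes rose in 2, HTB1 (1.49 ± 0.11) and HHT2 (nearly 2-fold), and fell in 5 of 9 cases. Genes of the a mating type rose in 2 and fell in 3 of 6 cases (2 and 4 adjusted over the list alone), with MFA1 at -1.26 ± 0.10 and MFA2 at -1.19 ± 0.11. Those of the other mating type rose in 0 and fell in 2 of 4, MF(ALPHA)2 at -0.71 ± 0.20 and STE3 at -0.70 ± 0.12, which were -0.02 and -0.02 (adjusted p = 0.918 and 0.936) with arrays scaled to the poly-A spike-in controls. No list of this paragraph passed, the other adjusted p running from 0.0937 to 0.852. The larger side of the counts turned or evened out with at least 1 other scaling for the TCA cycle, autophagy, hypoxic, stationary phase, histone and both mating type lists. The median was above 0 and the mean below it for the TCA cycle (0.19 and -0.15), autophagy (0.15 and -0.10) and hypoxic genes (0.27 and -0.12).

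The test passed 3665 of 5449 genes (67.3%) in limma, 2430 higher and 1235 lower in Rho0 low density, with a median size of 0.88 log2 among them and a median change of all genes of 0.25. At least 2-fold changes numbered 962 up and 549 down, and 13 lists were called, 4 up and 9 down. Of these 0 kept the call with an estimated correlation, and 10 of 100 splits of the 10 arrays gave as many. The split of called genes depended on the scaling, with 1875 higher and 1574 lower after quantile normalization of the S. cerevisiae genes alone, 1728 and 1775 with arrays shifted to the same S. cerevisiae median, and 3955 and 464 with arrays scaled to the poly-A spike-in controls. At least 2-fold rises numbered 599 with arrays shifted to the same S. cerevisiae median, and 2537 rises and 249 falls were found with the poly-A scaling.

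The third comparison set Rho0 low density against WT high density, so that genotype and density both differed. MSF1 (YPR047W) rose 59.1-fold, from 2.62 ± 0.25 to 8.51 ± 0.08 (mean ± SD, n = 5), and SUC2 (YIL162W) 43.7-fold from 7.35 ± 0.28 to 12.80 ± 0.11. MPC2 stood at 5.10 ± 0.11 log2 (difference ± SE) and GSY2 at 4.95 ± 0.14. ADH2 fell 295.6-fold, from 13.78 ± 0.08 to 5.57 ± 0.27, PUT4 (YOR348C) 105.8-fold, and FDH1, POX1 and PDR12 stood at -5.92 ± 0.13, -5.75 ± 0.12 and -5.64 ± 0.16. No group values of these 9 genes overlapped, and their limma adjusted p was at most 1.04e-15.

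Proteasome genes rose in 30 of 33 cases and fell in 0, with PRE3 at 3.65 ± 0.16 and PRE5 at 3.16 ± 0.18 (adjusted p = 5.6e-09; adjusted p = 0.318 with an estimated correlation). The list changes of this comparison went with a mean 3′ minus 5′ difference of 7 control messenger RNAs greater in Rho0 by 0.522 (exact p = 0.00794). That mean was chosen after the data were seen, and its p was not adjusted. Of these RNAs TDH1 alone went the other way (1.39 in WT high density and 0.621 in Rho0), and ACT1 hardly changed (1.57 and 1.61). Heat shock genes rose in 20 and fell in 2 of 23, with SSA2 at 3.95 ± 0.13 and SSA4 at 3.71 ± 0.14 (adjusted p = 5.88e-06; adjusted p = 0.327 with an estimated correlation). Trehalose and glycogen genes rose in 14 and fell in 2 of 18, with PGM2 at 3.31 ± 0.11 (adjusted p = 0.00035; adjusted p = 0.327 with an estimated correlation). Mitochondrial ribosome genes rose in 43 and fell in 5 of 65 (43 and 6 adjusted over the list alone), with RSM19 at 3.66 ± 0.14 and MRPS35 at 3.24 ± 0.13 (adjusted p = 0.000165; adjusted p = 0.379 with an estimated correlation). Pleiotropic drug resistance genes rose in 8 and fell in 2 of 13, with PDR15 at 2.69 ± 0.11 and TPO1 at 2.03 ± 0.13, at an adjusted p = 0.0481 (adjusted p = 0.327 with an estimated correlation) that reached 0.0666 without WT high density replicate 4.

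Ribosome biogenesis genes fell in 28 and rose in 1 of 34 cases (29 and 1 adjusted over the list alone), with NOG1 at -2.83 ± 0.17 and SSF1 at least 5.29-fold lower (adjusted p = 1.66e-07; adjusted p = 0.217 with an estimated correlation). Cytosolic ribosomal protein genes fell in 83 and rose in 11 of 127, with RPS14B at -3.85 ± 0.12 and RPS11A at -3.17 ± 0.15 (adjusted p = 2.23e-07; adjusted p = 0.457 with an estimated correlation). Fatty acid oxidation and peroxisome genes fell in 15 and rose in 3 of 23, with CTA1 at -4.68 ± 0.19 (adjusted p = 0.00078; adjusted p = 0.345 with an estimated correlation). Hexose transporter genes fell in 10 and rose in 2 of 14, with HXT10 at -3.97 ± 0.18 and the galactose permease gene GAL2 at -3.96 ± 0.16 (adjusted p = 0.00597; adjusted p = 0.345 with an estimated correlation). Glyoxylate cycle and gluconeogenesis genes fell in 8 and rose in 3 of 14, with ADY2 at -5.26 ± 0.14 and FBP1 at -4.26 ± 0.17 (adjusted p = 0.0323; adjusted p = 0.457 with an estimated correlation). The 4 genes of the other mating type all fell, with MF(ALPHA)2 down 7.98-fold and STE3 at -1.01 ± 0.12, at an adjusted p = 0.0481 (adjusted p = 0.327 with an estimated correlation) that was 0.0538 without Rho0 low density replicate 1 and 0.0694 after quantile normalization of the S. cerevisiae genes alone.

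The respiratory chain list had 15 genes up and 15 down of 40 (15 and 16 adjusted over the list alone), with ATP2 at 2.43 ± 0.28 and COX9 at -2.24 ± 0.11. Its mean lay 0.04 log2 above the other genes while the camera test pointed down (adjusted p = 0.917). Antioxidant genes rose in 17 and fell in 5 of 26 cases, with CTA1 and TSA2 (4.52 ± 0.23) the extremes (adjusted p = 0.0864), and TCA cycle genes in 11 and 4 of 16, with CIT1 at 2.45 ± 0.17 and CIT3 at -2.04 ± 0.11 (adjusted p = 0.211). Retrograde targets rose in 5 and fell in 1 of 7 cases (6 and 1 adjusted over the list alone), with ACO1 at -1.98 ± 0.24, and stationary phase genes rose in 3 and fell in 9 of 13, with YGP1 at 4.94 ± 0.19 and SNO1 at -3.95 ± 0.15, both lists at an adjusted p = 0.0513. The retrograde list passed in some settings, as in a fit of only the 10 arrays compared (0.0496) and without the arrays numbered 1 (0.0397), and the stationary phase list did so with arrays scaled to the poly-A spike-in controls (0.0363). Reference transcripts rose in 5 and fell in 3 of 9 cases, with ACT1 at 3.20 ± 0.19 and TUB2 at 2.72 ± 0.16 (adjusted p = 0.312).

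Glycolysis and fermentation genes rose in 11 and fell in 5 of 21 cases, with HXK1 at 4.86 ± 0.20, and the test pointed up although the list mean lay 0.03 log2 under the other genes (a difference of -0.03). Iron regulon genes rose in 6 and fell in 8 of 23 (6 and 7 adjusted over the list alone), with ARN1 at -2.30 ± 0.11 and FTR1 at -2.05 ± 0.15. Autophagy genes rose in 6 and fell in 11 of 27, with APE1 at 3.72 ± 0.18 and ATG1 at -2.78 ± 0.17. Amino acid biosynthesis genes rose in 15 and fell in 18 of 45, with ILV3 at -2.98 ± 0.12 and CPA1 at -2.82 ± 0.29. Ergosterol genes rose in 13 and fell in 4 of 24, with ERG27 at 1.85 ± 0.14 and ERG6 at 1.71 ± 0.15. Hypoxic genes rose in 7 and fell in 8 of 16, with COX5B at 2.02 ± 0.15 and AAC3 at 1.68 ± 0.19, and their median of -0.32 and mean of 0.02 differed in sign. Cell cycle genes rose in 8 and fell in 13 of 33, with CLN3 at -1.62 ± 0.21 and RFA1 at 1.60 ± 0.20. Histone genes rose in 6 and fell in 2 of 9, with HHT2 at 2.24 ± 0.10 and HTB1 at 1.31 ± 0.11. Genes of the a mating type rose in 4 and fell in 1 of 6, with STE6 at 1.88 ± 0.14 and STE2 at 1.31 ± 0.14. Sporulation genes rose in 5 and fell in 7 of 17 (6 and 7 adjusted over the list alone), with IME1 at -2.56 ± 0.23 and DMC1 at -1.96 ± 0.12. These 10 lists had an adjusted p from 0.118 to 0.842, and of them the histone list passed with the mean of the probe sets of a gene (0.04). The larger side of the counts turned with at least 1 other scaling for the iron, autophagy, amino acid, hypoxic, cell cycle and sporulation lists. The respiratory chain list, with 15 up and 15 down, had no larger side.

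In this comparison 3944 of 5449 genes (72.4%) passed in limma, 2067 higher and 1877 lower, with 1109 and 969 at 2-fold or more. The median size of the called changes was 1.05 log2. Of the 28 lists 12 were called, 6 up and 6 down, 1 kept its call with an estimated correlation, and 6 of 100 splits of the 10 arrays gave as many. With arrays scaled to the poly-A spike-in controls 2727 genes were higher and 1022 lower, with 1723 and 585 at 2-fold or more. The split turned with arrays shifted to the same S. cerevisiae median, to 1811 higher and 2197 lower, with 977 and 1146 at 2-fold or more.

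Changes from WT high density to WT low density and from WT high density to Rho0 low density were correlated across genes (Pearson r = 0.652, Spearman rho 0.631), where genes are not independent replicates. The shared WT high density arrays alone gave r = 0.5 in simulated data without effects. That value does not depend on the size of the noise, so it does not measure their part in the observed r. The covariance was 0.834, against 0.0134 in the simulated data. With the WT high density arrays split between the comparisons r averaged 0.624 over 20 splits, between 0.535 and 0.679. At 2-fold, 414 genes rose in both (129.8 if the calls were independent) and 510 fell in both (157.7). Opposite changes were found for 27 genes that rose and then fell (113.5) and 7 that fell and then rose (180.5). The shared arrays contribute to these counts. Of the 638 genes that rose at least 2-fold in WT low density, 507 were also called higher in Rho0 low density than in WT high density, 256 rose further from WT low density to Rho0 and 248 fell back. Of the 887 that fell, 717 were also called lower in Rho0 low density, 184 fell further and 394 rose back. For comparison, 1235 of all 5449 genes fell and 2430 rose from WT low density to Rho0 low density. The shares among the 887 lie near the general ones. Among the 638, falling back was more frequent than falls in general (248 of 638 against 1235 of 5449). At 2-fold each way, 157 genes rose and then fell (64.28 if the calls were independent), and 168 fell and then rose (156.6). Counts of genes moving further or back share the WT low density arrays, which favours reversals. The WT high density arrays are shared by the counts of 507 and 717. Changes from WT high to WT low density and from WT low density to Rho0 gave r = -0.121 (rho -0.0898), and -0.106 on average with the shared WT low density arrays split. Simulated data without effects gave r = -0.501, which again does not measure the part of the shared arrays in the observed r. The covariance was -0.118, against -0.0135 in the simulated data. Both relations were computed as 1 family of 2, without a test.

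The 1746 probe sets for the fission yeast Schizosaccharomyces pombe, which should find no target, gave 30 calls in the first comparison (29 higher), 69 in the second (all lower) and 1 in the third. With 1 array left out the counts ran from 12 to 62, from 14 to 91 and from 1 to 2. In limma 0 of them reached 2-fold in any comparison, and 289, 377 and 128 had an unadjusted p under 0.05. With arrays shifted to the same S. pombe median the first and second counts were 7 and 7.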

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

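The tests of explanations in this part were chosen after the results were seen. A value was picked out where 1 of the 5 arrays of a group lay far from the other 4 by Dixon's rule, which picks out about 1 in 20 groups by chance. Of 561 group values 57 were picked out against 28 expected by chance, and 30 of the 57 belonged to Rho0 low density replicate 1.

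In Rho0 low density replicate 1 the list means (log2) that lay above the other 4 arrays were respiratory chain 9.797, TCA cycle 9.708, retrograde targets 10.3, mitochondrial ribosome 7.035, cytosolic ribosomal proteins 8.145, trehalose and glycogen 9.954, heat shock 11.02, antioxidant defence 9.572, fatty acid oxidation 7.098, autophagy 7.058, proteasome 9.206, ergosterol biosynthesis 7.679 and a mating type genes 7.537. Genes above the other 4 arrays were AHP1 13.55, another gene 8.766, CIT1 11.99, CPA1 4.72, ERG27 8.649, HSP82 11.09, IDH2 8.047, MRPL4 6.964, MRPS16 9.996, MVD1 5.715, RPL38 9.572, SSA4 12.62, STE2 7.934 and SUC2 13, and genes below them were MCH2 6.611, MEP2 6.331 and NCA3 8.11. Mixed-in WT low density cells or RNA would move this array towards WT low density, but across genes its deviation rose with the Rho0 change. The slope was 0.0755 against -0.0435 to -0.00693 in the other 4 arrays. This argues against such mixing as the main source of its deviation. A small share hidden under another deviation stays possible, and mixing with WT high density was not tested. A fainter array could not be tested, since RMA had set all arrays to the same distribution of probe signals. The hybridization controls of replicate 1 lay at -0.338 from the mean of the others, whose own deviations ran from -0.42 to 0.37. Its poly-A spikes lay at -0.469, below the other 4 (-0.0492 to 0.337). No biological explanation was tested.

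In the remaining Rho0 arrays the values picked out were PRB1 10.66 in replicate 2, RPL23A 9.407 in replicate 3, and MSF1 8.361 and PDR5 12.1 in replicate 5. In WT high density they were genes of the other mating type 5.484, another gene 7.007, COX19 5.53 and PRE9 5.601 in replicate 1, OLE1 10.7 and PDR12 12.67 in replicate 2, the 25S 5′ probe set 7.648, glycolysis and fermentation 11.25, CAX4 4.735 and TSA2 6.47 in replicate 3, and ERG6 3.58 and PIR1 7.413 in replicate 5. In WT low density they were COX19 8.83, EMP46 6.047, FBP1 9.386, MRS4 9.286, PRE3 9.38 and SNZ1 11.46 in replicate 1, COX5B 8.906 in replicate 2, GSY2 9.036 in replicate 3, ERG5 5.931 in replicate 4, and AIM17 11.95 and RPS11A 6.344 in replicate 5.

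Signals outside the compared genes also differed between groups. The 25S ribosomal RNA probe sets were higher in WT low density than in WT high density by 3.49 log2 for the 5′ part and 3.18 for the middle. The hybridization controls differed by 0.159. They could not test for brighter WT low density arrays as a whole, since RMA had set all arrays to the same distribution of probe signals. Shorter RNA in the groups with little 5′ signal could not be decided. The mean 3′ minus 5′ difference of 7 control messenger RNAs was greater in Rho0 low density than in WT low density by 0.263 (exact p = 0.0238). This came mostly from SRB4 (2.89 in WT low density and 4.96 in Rho0). EAF5, RIP1 and WBP1 rose less, and ACT1 (1.9 to 1.61), SPT15 (6.96 to 6.42) and TDH1 (0.766 to 0.621) fell. The mean was smaller in WT high density than in WT low density (a difference of 0.258, exact p = 0.0873). Group means of that measure were 2.80 in WT high density, 3.06 in WT low density and 3.32 in Rho0 low density. Whether ribosomal RNA differs in the cells was not tested.

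The poly-A spike-in probe sets were lower in Rho0 low density than in WT low density by a difference of -0.683 log2. Fainter Rho0 arrays could not be tested, since RMA had set all arrays to the same distribution of probe signals. The spikes minus the hybridization controls differed by -0.305 (exact p = 0.135), so that a change of the spikes alone was not shown. The median yeast gene rose by 0.946 against the spikes, which is what more messenger RNA per total RNA in Rho0 cells would give, but the labels do not state how much spike was added to each sample, so that this could not be decided.

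Probe sets without a gene name were not part of the comparisons. Of 3517 such probe sets 388 were above the background level, and 68, 67 and 94 were called at 2-fold or more in limma in WT low against WT high density, Rho0 against WT low density and Rho0 against WT high density.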

How the results depend on the processing

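Settings named as added below were chosen after the data were seen. No named gene or list that passed changed the direction of its test in any setting. Shifting whole arrays by a constant leaves a list's mean minus the other genes as it was, so those settings say little about list directions. In Rho0 against WT low density, however, the counts of risen and fallen members turned for 8 lists called down with arrays scaled to the poly-A spikes and for the amino acid list also with the S. pombe shift. The split of called genes there went from 2430 higher and 1235 lower to 1728 and 1775 with the same S. cerevisiae median. Leaving out 1 array at a time kept all 2050 named gene results and 825 list results on their side of the threshold, with 9 list calls lost and 6 gained. The named genes were chosen from these data for their large changes, so that few of their calls could be lost. Other settings kept 2456 named gene results and 1084 list results, with 48 list calls lost and 44 gained. The 2 gene calls lost were MF(ALPHA)2 and STE3 in Rho0 against WT low density, both with arrays scaled to the poly-A spikes (added).

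The choice of the list test moved the list counts most. With an estimated correlation 2, 0 and 1 lists were called in the 3 comparisons against 16, 13 and 12, and fry, which asks only whether a list moves on balance one way, called 24 in Rho0 against WT low density and 25 in Rho0 against WT high density. Scaling moved the 2-fold counts. In Rho0 against WT low density 599 genes were higher with arrays shifted to the same S. cerevisiae median, and 2537 higher and 249 lower with the poly-A scaling, which gave 1723 higher and 585 lower in Rho0 against WT high density. The cause was not tested. S. pombe calls were 7 and 7 in WT low against WT high density and Rho0 against WT low density with arrays shifted to the same S. pombe median. Without 1 array they ran from 12 to 62, from 14 to 91 and, in Rho0 against WT high density, from 1 to 2. The relation of the changes from WT high to WT low density and from WT low density to Rho0 was r = -0.0613 after quantile normalization on S. cerevisiae genes, and from -0.137 to -0.104 without 1 array.

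With the replicate number as a replicate block 3776, 3769 and 4047 genes were called and the 2-fold counts were unchanged. The retrograde list in Rho0 against WT high density then passed (adjusted p = 0.0465), the 1 list call that the block changed. Deviations from the group means correlated over 0.1 for 4 of 5 same-numbered arrays of WT low and WT high density (0.0386 for number 2), and 3 of 5 correlated best with their own number. In the comparisons with Rho0 low density 2 of 5 and 1 of 5 did so, so that whether the numbers pair the wild-type samples stays open. Without the 3 arrays numbered 1 (added) 3664, 3555 and 3862 genes were called. Settings without the mitochondrial DNA genes gave no value, since the annotation named no such gene. Signal near the background level limits fold changes of weak genes: 4860 of 5449 genes were above it in WT low density on average.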

Other observations

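The tests in this part were chosen after the results were seen, except the splits of the arrays, and the nitrogen list was put together after the largest falls were seen but before it was tested. Permeases for nitrogen compounds filled much of the list of falls from WT low density to Rho0 low density. Besides PTR2, MEP2, PUT4 and MUP3 the ammonium permease genes MEP1 (-3.73) and MEP3 (-3.76), the amino acid permease gene AGP1 (-4.19), the glutamine synthetase gene GLN1 (-3.52) and the permease genes UGA4 (-2.95) and GAP1 (-2.05) fell, while GDH2 (1.21) and UGA1 (1.02) rose. Many genes of this kind are known to be repressed where good nitrogen sources are plentiful. Of 20 genes of this group that had not prompted the question 10 fell and 3 rose (camera adjusted p = 0.000347), but with an estimated correlation the adjusted p = 0.194, so that a shift of the group stays possible and undecided.

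Of 14 targets of the regulator Adr1, 7 fell and 2 rose, and of the 10 left without the genes that prompted the question, ADH2, FDH1, ADY2 and POX1, 3 fell and 2 rose (adjusted p = 0.0624, and 0.471 with an estimated correlation), which leaves a lower activity of the group undecided. Actin and tubulin genes apart from ACT1 and TUB2 rose in 19 and fell in 2 of 26 cases, among them TPM1 (2.10), ARC15 (2.03), CAP1 (1.76) and COF1 (1.76), and TUB3 fell (-1.69). Their adjusted p = 0.0145 became 0.467 with an estimated correlation, so that a rise of the group stays undecided.

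WT low density was not simply between the other groups. At least 2-fold above both lay 157 genes (2.88%) and below both 168 (3.08%), 325 together, more than the 1% set as the limit. As far as these differences come from the cells, they argue against a mere mixture of cells like the other groups. The 25S 5′ signal was also highest in WT low density (11.36 against 7.87 in WT high density and 7.75 in Rho0 low density). An effect of the RNA or arrays of this group could likewise put genes outside both others, so that a mixture is not excluded. GLN1 read 6.43 in WT high density, 9.41 in WT low density and 5.89 in Rho0 low density.

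The chromosome median farthest from the other genes differed by -0.139 in Rho0 against WT low density (chromosome XIV). In Rho0 against WT high density it differed by 0.212 (chromosome VI), and both lay within the 0.5 set as the limit. This argues against a whole chromosome gained or lost in most Rho0 cells of all replicates. A change in single replicates, in a small share of the cells or in part of a chromosome was not tested. Genes near chromosome ends, 10 at each end, rose in 131 and fell in 47 of 235 cases, with an adjusted p = 0.118 and 0.483 with an estimated correlation, in a comparison where 2430 of 5449 genes rose. With single-gene probe sets alone 96 rose and 43 fell of 183, the mean over other genes was 0.143 in place of 0.243, and the adjusted p was 0.429 and 0.692. A rise near the ends stays undecided. Transcripts running on from the gene upstream stay undecided. The changes of neighbours on the same strand correlated less than those of divergent neighbours, with a largest excess of -0.03, but divergent neighbours share a promoter region, and the same-strand pairs exceeded convergent pairs in 2 of 3 comparisons (0.104 against 0.0929, 0.0862 against 0.077, and 0.0526 against 0.0709).

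Before the splits were run it was set that a result would count as possible by chance where 5% or more of 100 of the 126 ways to split the 10 arrays gave a count as large. For the counts of genes called, 2-fold higher and 2-fold lower, 1 of 100 splits (the real one) did so in WT low against WT high density, where the highest other counts were 1144, 240 and 247, and likewise 1 in Rho0 against WT low density and 1 in Rho0 against WT high density, where the highest other count was 0. For lists called it was 4, 10 and 6 of 100 splits, with highest other counts of 16, 14 and 13, so that chance is not excluded for the number of lists called in the last pair of comparisons. For S. pombe probe sets it was 1, 1 and 3, with highest other counts of 11, 3 and 1.

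Some genes of other cell types had high signals in these haploid cells of mating type a, while 4 of 17 sporulation genes and 1 of 4 genes of the other mating type were not above the background level. Means of the sporulation list were 4.18, 3.35 and 3.86 in WT high density, WT low density and Rho0 low density, and STE3 read 3.94, 3.63 and 2.93. SAG1 read 10.27, 8.97 and 9.34, DMC1 8.50, 6.74 and 6.54, and DIT1 8.19, 7.59 and 9.15, in the same order.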
